A study of Mus musculus with 42 samples.

How the data were processed

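The series holds 42 Affymetrix mouse expression arrays, 3 in each of 14 groups. Per the labels' protocols, slices of forebrain were microdissected, digested with pronase E and triturated, and fluorescent cells were picked by hand, 27 to 120 per array. RNA was then extracted, amplified and turned into biotinylated cRNA, per the labels. The groups with Homog in their names hold dissociated cells that were not sorted, per the labels. The series design states that the replicates of a type come from different animals, and all sorted mice are labelled male. Depth does not apply to arrays; the number of arrays limits the precision.

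The values used are linear intensity values as deposited, in a single table of 22690 probe sets by 42 arrays. They run from 1 to 22818.24, with array medians between 285.83 and 330.39. How the probe signals were summarised and scaled into these intensity values before they were deposited is not given in the sources used here. The raw array images were not used here. Scan day, array lot and sorted-cell number were read from the array records deposited with the series. Those records hold 21 scan days, 16 with more than 1 array, 3 scan years and 11 lots, and 1 array is dated by hybridization instead of scan. They also mark 2 arrays as abnormally amplified (YFPH_Hip array 1 and YFPH_Amy array 2) and 1 as sorted by a new method (YFPH_Cg array 3).

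Each value was turned into log2 of the intensity plus 16. The 64 control probe sets were removed, apart from the Gapdh control sets used to measure the log2 signal of the 3' over the 5' end. Of the others 20380 had exactly 1 gene symbol, 691 had several and 1555 were not in the annotation table, which dates from 2016; only those with 1 symbol were used. Gene identifiers of 20351 were found in the RefSeq table, and 0 symbols changed. The probe set with the highest mean stood for each of 12393 genes. Genes whose mean lay under the 25th percentile (log2 7.77, intensity 203) were not tested, which left 9295.

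A linear model with a mean per group was fitted over the 42 arrays with limma 3.58.1 in R 4.3.3, with 28 residual degrees of freedom and moderated variances that follow the mean (median prior degrees of freedom 6.07). Contrasts were the mean of 4 pyramidal groups minus the mean of 6 interneuron groups, 15 pairs of groups, and 3 interactions of region and line. The amygdala groups were left out of the class contrast because their labels do not give a class. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p below 0.05. A moderated F test asked for any difference among the 12 sorted groups. A gene was type-specific if it was higher in a sorted group than in each of the other 11, from the highest of the 11 p-values, adjusted over all genes and groups. Similarity of arrays was tested by permuting group labels 100000 times.

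Gene lists were written from textbook knowledge: GABA synthesis and transport, GABA transcription factors, glutamatergic genes, neuropeptides, markers of parvalbumin, somatostatin, and VIP and CCK interneurons, layer 5, layer 6, hippocampal pyramidal, thalamic and midbrain transcription factors, striatal GABA genes, astrocytes, oligodendrocytes, microglia, endothelial and mural cells, blood, early response genes and neurofilaments. Families were voltage-gated potassium channels, sodium and calcium channels, GABA-A receptors, ionotropic glutamate receptors, cadherins and protocadherins, oxidative phosphorylation and cytosolic ribosome. The lists hold 369 tested genes, and 23 of these are in more than 1 list. Lists with at least 5 tested genes, 24 of the 26, were tested with camera of limma in 16 comparisons at a preset correlation of 0.01 between genes, with 384 tests adjusted together, and again with the correlation estimated from the data. The lists of GABA synthesis (4 tested genes) and blood (2) were only counted.

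Genes were named by a rule: per comparison up to 8 called genes in each direction with the largest difference, from those whose arrays do not overlap between a pair of groups or, for the class contrast, whose group means do not overlap. For interactions overlap was not considered. Per list the rule takes up to 4 members with the largest difference, and per type up to 3 specific genes by the gap to the next type. Sst, Pvalb, Gad1, Gad2, Vip, Cck, Npy and Thy1 were reported whatever their values; Slc17a7 had no probe set of a single gene and was not analysed here.

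Alternatives planned in advance were quantile normalization, median centring, no filter, a filter at the 50th percentile, a floor at the 25th percentile, every probe set, the replicate number as a block, scan day as a random or fixed block, each array left out in turn, the compared arrays only, and an estimated correlation for lists. Where they applied, cortical groups only, each cell type as 1 replicate and age as a block were added. Chosen after seeing the data were scan year as a block, the 2 abnormally amplified arrays left out, the second scan year only, YFPH_Cg array 3 left out, the Gapdh 3' to 5' signal as a covariate, and list shifts with scan day as a block. The fits with blocks used limma with statmod 1.5.0.

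Replicate numbers were checked for pairing in 15 pairs of groups, from the correlation of each array's deviations from its group mean. Every correlation was over 0.1 in 1 pair of groups, the unsorted cells (0.242, 0.225 and 0.178), where each array correlated best with its own number. This pairing comes from the data; the labels do not state it.

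The code was tested on simulated data before use, with a seeded set of genes changed in 1 group. In GIN_Cg minus G42_Cg it called 96% of genes changed by log2 1 and 100% of those changed by log2 2, with 12 unchanged genes called. For specific genes it called 77% and 99%, with 0 other calls, and the F test called 96.25% of changed genes and 18 unchanged ones. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.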

Results

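Gene expression was measured on 42 single-colour Affymetrix mouse arrays, 3 for each of 14 groups of cells from the adult mouse forebrain. In 12 groups the RNA came from fluorescent neurons picked by hand after slices were dissociated, 27 to 120 cells per array, and was amplified before labelling. By their labels, GIN_Hip and GIN_Cg were somatostatin interneurons of hippocampus and cingulate cortex, G42_Cg were parvalbumin interneurons of cingulate cortex, and G42_LGN were interneurons of the lateral geniculate nucleus. G30_Cg and G30_SS were interneurons of cingulate and somatosensory cortex from the G30 line, which also carries GFP. YFPH_Cg and YFPH_SS were layer 5 pyramidal neurons of the same cortical areas, YFPH_Hip were hippocampal pyramidal neurons, and CT6_Cg were layer 6 pyramidal neurons of cingulate cortex filled with beads from the thalamus. YFPH_Amy and G30_Amy were fluorescent amygdala neurons whose labels do not state a class. GIN_Homog_Cg and G42_Homog_Cg were unsorted dissociated cells of cingulate cortex. The replicates of a group came from different animals, and 3 arrays per group limit the precision of every estimate.

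The comparisons, gene lists and rules used here were written down before the data were examined. Differences are first minus second group in log2 of intensity plus 16, with array numbers and a standard error (SE) pooled over all groups. A gene is called higher or lower from its limma p, adjusted over 9295 tested genes in each comparison, and lists were tested with camera and adjusted together. Each list has a count adjusted over all genes and, beside it, a count adjusted over the list alone. For pairs of groups, genes named for the size of their difference are those whose arrays did not overlap between the groups.

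The marker genes separated the sorted groups along the lines of their labels. Sst, the somatostatin precursor, stood at log2 14.12 ± 0.06 (SD, n = 3) in GIN_Cg and 13.54 ± 0.18 in GIN_Hip, against 8.52 ± 0.10 in YFPH_Cg. Pvalb, a calcium buffer of fast-spiking cells, reached 13.42 ± 0.05 in G42_Cg, and also 11.72 ± 0.31 in GIN_Hip and 11.95 ± 0.83 in the pyramidal group YFPH_SS. Vip, a neuropeptide, was at 12.47 ± 0.30 in G30_Cg and 12.52 ± 0.68 in G30_SS, and at or under 7.87 in every other sorted group. Sst differed widely between the G30_SS arrays (11.70 ± 1.46). Thy1, a neuronal surface glycoprotein whose promoter drives YFP in the YFPH line, was between 14.36 and 14.43 in the 4 YFPH groups and at most 13.05 elsewhere.

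**Figure D1:**
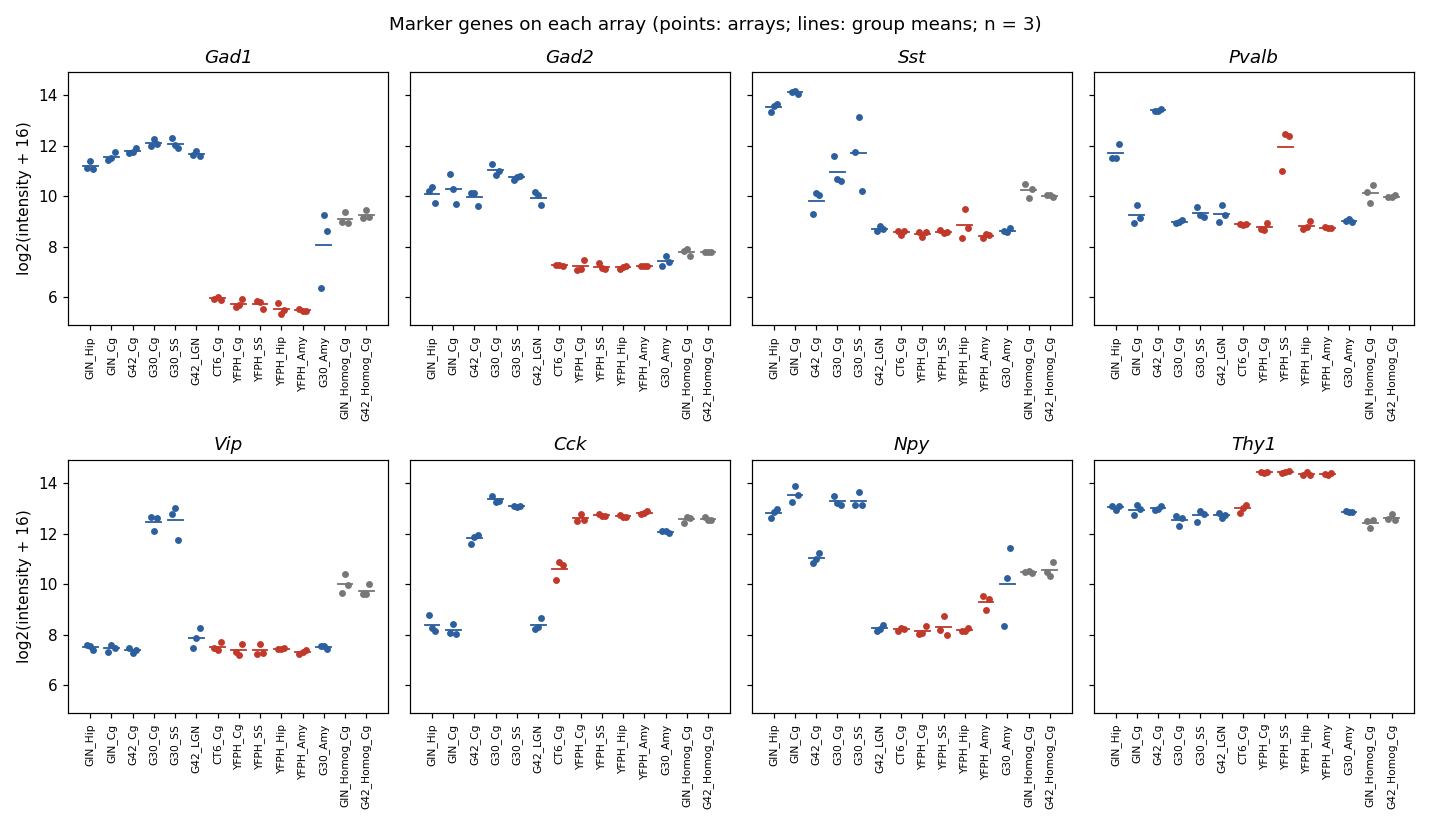
Points are arrays and lines are group means for 8 marker genes, with log2 (intensity + 16) on the vertical axis and the 14 groups on the horizontal axis.

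The arrays of a group resembled each other more than arrays of different groups. The mean Pearson correlation over the tested genes was 0.9733 within groups and 0.8891 between groups, a difference of 0.08426 (permutation of the group labels, one-sided p = 0.00001, the smallest value that 100000 permutations can give). For 36 of 42 arrays the most similar array was in the same group. The 6 others were 2 G30_SS arrays nearest to G30_Cg, 1 YFPH_SS array nearest to YFPH_Cg, and 3 unsorted arrays nearest to the other unsorted group.

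Pyramidal neurons had less of the genes of GABA synthesis and release than interneurons, and more of the glutamatergic genes. The comparison asked which genes separate the classes over several regions, in 4 pyramidal and 6 interneuron groups. Gad1, which makes GABA, was lower in pyramidal neurons by a log2 difference of -6.00 ± 0.15 (SE, n = 12 and 18 arrays, adjusted p = 5.22e-27), as were Slc32a1, the vesicular GABA transporter (-5.07 ± 0.13), and Gad2 (-3.12 ± 0.09). Dlx1, a transcription factor of interneuron development (-4.18 ± 0.11), and the kainate receptor gene Grik1 (-3.66) were lower too. Crym, which binds thyroid hormone, was higher by 5.71 ± 0.12 (52.4-fold, adjusted p = 7.16e-29), with Itpka, an inositol phosphate kinase of dendritic spines (3.85 ± 0.09), Fezf2, a transcription factor of subcortically projecting neurons (3.67 ± 0.13), and the tyrosine kinase gene Ptk2b (3.67 ± 0.10). Nrgn, a calmodulin-binding postsynaptic protein (3.30 ± 0.14), and the chemokine gene Cxcl12 (3.05) were also higher. Npy (-3.83 ± 0.16), Sst (-2.83 ± 0.16), Vip (-1.77 ± 0.10) and Pvalb (-0.72 ± 0.11) were lower. Cck (1.62 ± 0.07) and, through the YFPH groups, Thy1 (1.22 ± 0.05) were higher.

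The lists of cell identity followed the classes. All 4 measured genes of GABA synthesis and transport were lower (Gad1, Gad2, Slc32a1 and Abat), and all 12 glutamatergic genes were higher (12 over the list alone; list mean 1.83, adjusted p = 2.22e-15). Of 9 GABA transcription factors 6 were lower and 1 higher (6 and 2 over the list alone, mean -0.91, adjusted p = 0.000197). Of the layer 5 list 10 of 14 genes were higher (10 over the list alone, mean 1.64, adjusted p = 2.15e-10), and of the hippocampal pyramidal list 8 of 10 were higher and 1 lower (8 and 1 over the list alone, mean 1.26, adjusted p = 2.38e-06). The somatostatin list had 6 of 9 genes lower and 2 higher (the same over the list alone, mean -1.59, adjusted p = 7.69e-05), and the VIP and CCK list 9 of 12 lower and 1 higher (9 and 2 over the list alone, mean -0.90, adjusted p = 7.05e-05). The neurofilament list was higher (4 of 6 higher, 1 lower, the same over the list alone, adjusted p = 0.00123, adjusted p = 0.111 with an estimated correlation). The neuropeptide list was lower (9 of 15 lower, 3 higher, the same over the list alone, adjusted p = 0.0239, adjusted p = 0.0949 with an estimated correlation, 0.0888 without a filter and 0.591 with the 50th percentile filter). The parvalbumin list was lower (7 of 12 lower and 1 higher; 7 and 2 over the list alone, adjusted p = 0.0336, adjusted p = 0.0889 with an estimated correlation). No astrocyte, oligodendrocyte, microglia or endothelial list was called (adjusted p = 0.561, 0.704, 0.879 and 0.765). Of the 2 tested blood genes Slc4a1 was higher (0.30 ± 0.10), and that list is too small for a list test. Arc (2.27 ± 0.18) and Egr1 (1.40 ± 0.13), early response genes, were higher in pyramidal neurons, while their list was not called (adjusted p = 0.242).

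In total 4562 genes were called between the classes, 2044 higher and 2518 lower in pyramidal neurons (44.8% higher, and 50.5% with median centring), and 315 of them differed at least 2-fold (183 higher, 132 lower). With each cell type taken as 1 replicate 584 genes were called, all among the 4562, and Cck (adjusted p = 0.421), Pvalb (0.681), Sst (0.1) and Vip (0.367) were not; over the other alternatives their adjusted p went down to 2.46e-22, 9.26e-08, 6.28e-21 and 5.07e-20. The classes were spread unevenly over scan years, with 7 pyramidal and 0 interneuron arrays in the first. With scan year as a block 1926 genes were called, 1821 of them also called without it, and Pvalb was not (adjusted p = 0.0769). On the second-year arrays alone, 5 pyramidal and 18 interneuron, 2136 genes were called, 1960 of them shared, and Pvalb was not (adjusted p = 0.19). On the scan days with 1 array of each class, 80.4% and 74.5% of the 4562 kept direction.

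**Figure D2:**
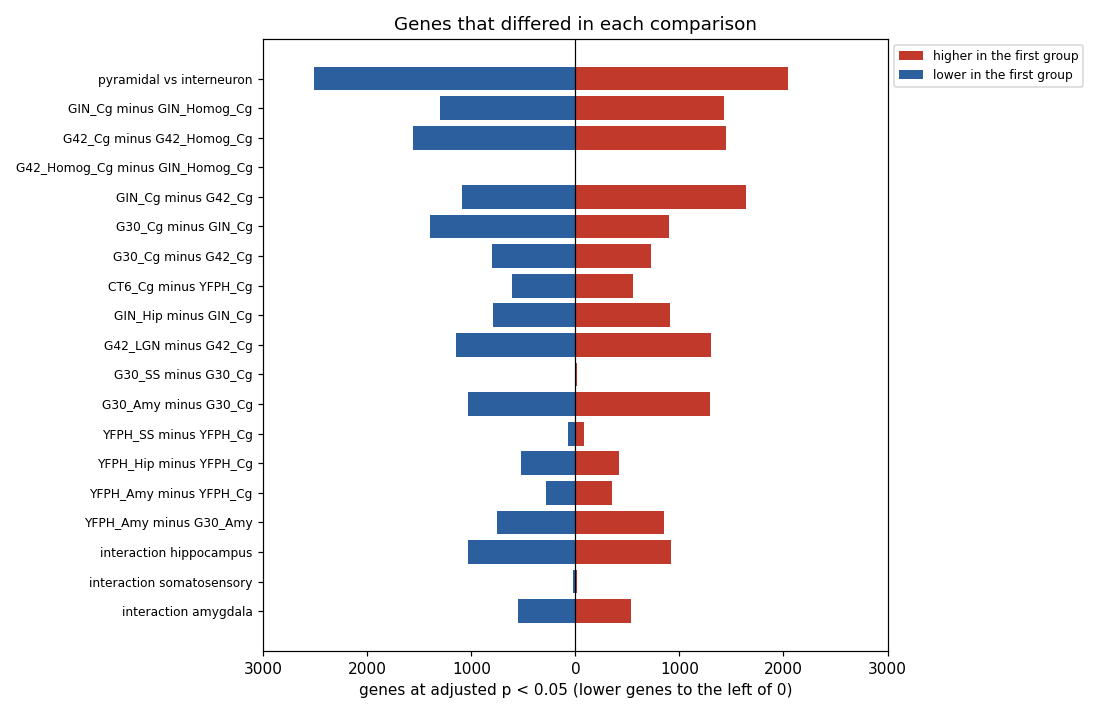
Bars give the number of called genes per comparison on the horizontal axis, with genes higher in the first group to the right of 0 and lower to the left.

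Somatostatin interneurons of cingulate cortex held more of their marker genes and less of glial and pyramidal genes than unsorted cells. The comparison asked which genes the sorting enriched. Sst was higher in GIN_Cg than in GIN_Homog_Cg by 3.88 ± 0.36 (SE, n = 3 and 3, 14.8-fold, adjusted p = 1.21e-10). Dlx1 (3.64 ± 0.24), Calb2, the calcium buffer calretinin (3.52 ± 0.37), and the neuropeptide gene Npy (3.06 ± 0.35) were higher, as were Gad1 (2.47 ± 0.33) and Gad2 (2.50 ± 0.19). Apoe, a lipid carrier made by astrocytes, was at -6.08 ± 0.37 (67.6-fold lower, adjusted p = 4.54e-15), Aldoc, a glycolytic enzyme of astrocytes, at -4.93, and Crym at -4.99 ± 0.26. Cck (-4.39 ± 0.15), Vip (-2.53 ± 0.21) and Pvalb (-0.88 ± 0.23) were lower as well, and Thy1 was higher (0.53 ± 0.10).

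All 4 GABA genes were higher in GIN_Cg, and so were the somatostatin list (7 of 9 higher, 7 over the list alone, mean 1.81, adjusted p = 2.01e-06) and the GABA transcription factors (6 of 9 higher, 6 over the list alone, adjusted p = 6.99e-05). All 12 glutamatergic genes were lower (12 over the list alone, mean -1.77, adjusted p = 6.87e-14). The layer 5 list had 11 of 14 genes lower and 1 higher (the same over the list alone, adjusted p = 1.95e-08), the layer 6 list 6 of 11 lower and 1 higher (the same over the list alone, adjusted p = 0.00554), and the hippocampal pyramidal list 5 of 10 lower and 1 higher (6 and 1 over the list alone, adjusted p = 0.000197). Lists of other cell types were lower, with the same counts over each list alone: astrocytes (6 of 10; mean -1.81, adjusted p = 1.48e-07), microglia (7 of 10, among them Ctss and C1qa; adjusted p = 1.09e-06), oligodendrocytes (4 of 5, among them Mbp and Cnp; mean -1.55, adjusted p = 0.000346) and endothelial and mural cells (5 of 8, among them Rgs5 and Kdr; mean -0.90, adjusted p = 0.000633). Sodium and calcium channel genes were higher (8 of 23 higher, 1 lower, the same over the list alone, adjusted p = 0.00355), with Cacna2d3 at 2.28 and Scn1a at 1.46. Of the GABA-A receptor genes 3 of 8 were lower (3 over the list alone, adjusted p = 0.022). This list call ended without a filter (0.209), with every probe set (0.0609) and with the Gapdh covariate (0.071). In all, 2731 genes were called (1426 higher, 1305 lower), 538 of them at least 2-fold. With the Gapdh covariate 1773 genes were called (1647 shared). The Gapdh log2 3' to 5' signal was 3.21 ± 0.37 (SD) in GIN_Cg and 2.0 ± 0.21 in GIN_Homog_Cg. With scan day as a fixed block 2746 genes were called. Within the 3 shared days 99.3%, 99.6% and 99.7% of the 2731 kept direction, which tests little, as they were chosen on these arrays. Arrays did not overlap for 43.5% of tested genes, against 10% by chance for 3 and 3 arrays.

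Parvalbumin interneurons of cingulate cortex, against their own unsorted cells, held more of the genes of the parvalbumin list. Pvalb was higher in G42_Cg by 3.42 ± 0.23 (SE, n = 3 and 3, 10.7-fold, adjusted p = 4.26e-14), with Kcnmb2, a subunit of calcium-activated potassium channels (3.46 ± 0.24), Cox6a2, a cytochrome oxidase subunit (3.04 ± 0.12), and Lhx6, a transcription factor of interneurons from the medial ganglionic eminence (2.68 ± 0.11). Sst (-0.20 ± 0.36, adjusted p = 0.703) and Npy (0.46 ± 0.35, adjusted p = 0.342) were not called against the unsorted cells. Apoe was at -6.13 ± 0.37 (70-fold lower), Crym at -5.26, and Mbp, a myelin protein gene, at -4.89 ± 0.32. Vip (-2.37 ± 0.21) and Cck (-0.78 ± 0.15, adjusted p = 5.25e-05) were lower, and Gad1 (2.55 ± 0.33) and Gad2 (2.17 ± 0.19) higher. Thy1 was higher by 0.36 ± 0.10 (adjusted p = 0.00537), a call that ended with scan day as a fixed block (0.131).

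The parvalbumin list had 9 of 12 genes higher (9 higher and 1 lower over the list alone, mean 1.55, adjusted p = 2.54e-09), and 49 of 77 oxidative phosphorylation genes were higher and 1 lower (54 and 1 over the list alone, mean 0.56, adjusted p = 2.72e-16). All 4 GABA genes were higher, although another probe set of Abat was called in the opposite direction, and 5 of 9 GABA transcription factors were higher (6 over the list alone, adjusted p = 0.00129). The glutamatergic list had 11 of 12 genes lower (mean -1.73, adjusted p = 9.33e-10), the hippocampal pyramidal list 10 of 10 (adjusted p = 4.94e-08), the layer 6 list 8 of 11 (adjusted p = 6.11e-05), and the layer 5 list 11 of 14 with 3 higher (adjusted p = 0.000251), each with the same counts over the list alone. Astrocyte (7 of 10, 7 over the list alone, adjusted p = 4.13e-05), microglia (7 of 10, 8 over the list alone, adjusted p = 6.64e-07), oligodendrocyte (4 of 5, 4 over the list alone, adjusted p = 6.11e-05) and endothelial (6 of 8, 6 over the list alone, adjusted p = 0.000654) genes were lower. The VIP and CCK list was lower (5 of 12, 5 over the list alone, adjusted p = 0.00542, adjusted p = 0.121 with an estimated correlation), and the neurofilament list was higher (4 of 6, 1 lower, the same over the list alone, adjusted p = 0.0303, adjusted p = 0.315 with an estimated correlation, 0.0602 with quantile normalization and 0.0535 with the 50th percentile filter). In all, 3010 genes were called, 1445 higher and 1565 lower (48.0% higher, and 62.7% with median centring). With scan day as a fixed block 2249 genes were called. Within the shared days 99.5% and 99.2% of the 3010 kept direction, which again tests little.

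The unsorted cells of both lines were close to each other. Asked whether the lines differ in unsorted cells, limma called 1 of 9295 genes, with 280 below an unadjusted p of 0.05. Serpina3n, a secreted protease inhibitor induced in reactive astrocytes, was lower in G42_Homog_Cg by -1.27 ± 0.22 (SE, n = 3 and 3, 2.41-fold, adjusted p = 0.0198). Over 18 alternatives its adjusted p ran from 0.00662 to 0.69, and the call ended with the compared arrays only (0.256) and without GIN_Homog_Cg array 3 (0.69, with 0 genes called), G42_Homog_Cg array 1 (0.208) or G42_Homog_Cg array 2 (0.0854). Without GIN_Homog_Cg array 1, limma called 2 genes. Gad1 (0.16 ± 0.33), Sst (-0.22 ± 0.36), Gad2, Pvalb, Vip, Cck, Npy and Thy1 were not called (adjusted p = 1.0 for each), nor was any list. The genes whose arrays did not overlap were 11.2% of those tested, near the 10% given by chance.

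Somatostatin and parvalbumin interneurons of the same cortex were compared to ask what separates these subclasses. Of the 4 GABA genes Abat was lower in GIN_Cg than in G42_Cg (-0.60 ± 0.16, adjusted p = 0.00574), while Gad1 (-0.23 ± 0.33, adjusted p = 0.627), Gad2 (0.35 ± 0.19, adjusted p = 0.164) and Slc32a1 (-0.14 ± 0.29, adjusted p = 0.75) were not called. Calb1, the buffer calbindin (4.51 ± 0.31, SE, n = 3 and 3, adjusted p = 2.2e-13), Reln, the matrix protein reelin (4.48 ± 0.31), Calb2 (4.33 ± 0.37), Sst (4.30 ± 0.36), Npy (2.52 ± 0.35) and the adenylyl cyclase gene Adcy2 (4.22) were higher in GIN_Cg. Prss23, a serine protease gene (-5.33 ± 0.45), Pvalb (-4.17 ± 0.23, adjusted p = 7.05e-16), Lpl, lipoprotein lipase (-4.16), Cck (-3.63 ± 0.15) and Gabrd, a subunit of extrasynaptic GABA receptors (-3.45), were lower. Vip and Thy1 were not called (adjusted p = 0.772 for both).

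The somatostatin list was higher in GIN_Cg (4 of 9, the same over the list alone; median 0.34, mean 1.80, adjusted p = 0.000639) and the parvalbumin list lower (7 of 12; 8 lower and 1 higher over the list alone, mean -1.29, adjusted p = 6.7e-09). Oxidative phosphorylation genes were lower (44 of 77 lower, 2 higher; 51 and 3 over the list alone, mean -0.41, adjusted p = 2.22e-15). Cadherins and protocadherins were higher (11 of 26; 11 higher and 1 lower over the list alone, adjusted p = 0.00885, adjusted p = 0.061 with an estimated correlation), among them Cdh22 (3.24), Cdh8 (1.77) and Cdh11 (1.63). Of 2735 called genes 1642 (60%) were higher and 1093 lower. With median centring 38.0% were higher, and the median difference over all genes moved from 0.067 to -0.041. With the Gapdh covariate 1328 genes were called, 1238 of them shared. The Gapdh log2 3' to 5' signal was 3.21 ± 0.37 (SD) in GIN_Cg and 1.98 ± 0.20 in G42_Cg.

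The G30 interneurons of cingulate cortex were compared with each of the other lines to ask what sets them apart. Against GIN_Cg, Cck, a neuropeptide of basket cells, was higher by 5.18 ± 0.15 (SE, n = 3 and 3, adjusted p = 1.16e-24), Vip by 5.00 ± 0.21 (32.1-fold), Cadps2, a priming factor for dense-core vesicles, by 5.46, Tac2, the neurokinin B precursor, by 5.09, and Lamp5, a marker of neurogliaform cells, by 4.93. Lgals1 (-4.44 ± 0.27), Sst (-3.14 ± 0.36), Nefm (-3.36 ± 0.29) and Lhx6 (-2.81 ± 0.11) were lower. Nfix was at 5.63 ± 0.36, while another probe set of this gene was called in the opposite direction. Gad2 was higher by 0.73 ± 0.19 (adjusted p = 0.0043), a call that ended with the compared arrays only (adjusted p = 0.101) and without GIN_Cg array 3 (0.0861), with a lowest adjusted p of 6.37e-05 over 17 alternatives. Thy1 was lower (-0.41 ± 0.10, adjusted p = 0.00364), but not called with the compared arrays only (0.0598) or without G30_Cg array 2 (0.0583). Pvalb, Gad1 and Npy were not called (adjusted p = 0.454, 0.239 and 0.632). The VIP and CCK list was higher (8 of 12 higher, 2 lower, the same over the list alone, mean 2.18, adjusted p = 9.98e-16), the neurofilament list lower (5 of 6; mean -1.60, adjusted p = 2.55e-06), and the somatostatin list lower (4 of 9; mean -1.07, adjusted p = 0.00155), with the same counts over the lists alone. The neuropeptide list tested higher with a mean of 0.93 and a median of -0.26, which differ in sign (5 of 15 higher, 3 lower, the same over the list alone, adjusted p = 0.0239, adjusted p = 0.0949 with an estimated correlation, 0.0531 with median centring, 0.143 without a filter and 0.755 with the 50th percentile filter). The layer 5 list was higher through Id2 (3.95) and Parm1 (3.91) (6 of 14 higher, 2 lower, the same over the list alone, adjusted p = 0.0194, adjusted p = 0.19 with an estimated correlation). The blood gene Slc4a1 was lower (-0.62 ± 0.23). In all, 2296 genes were called, 902 higher and 1394 lower (39.3% higher, and 54.3% with median centring), and 1504 without G30_Cg array 2.

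Against G42_Cg, the same G30 neurons were higher in Vip (5.10 ± 0.21, SE, n = 3 and 3), Tac2 (5.32), Lamp5 (5.23), the chemokine gene Cxcl14 (4.23) and Reln (4.10), and in Npy (2.26 ± 0.35), Cck (1.55 ± 0.15) and Gad2 (1.08 ± 0.19). Pvalb was lower (-4.42 ± 0.23, adjusted p = 7.45e-17), with the neurofilament genes Nefm (-3.46) and Nefh (-3.14) and Ppargc1a, a coactivator of mitochondrial genes (-2.95), and Thy1 (-0.45 ± 0.10). Gad1 was not called (adjusted p = 0.618). Sst was at 1.16 (adjusted p = 0.0204), and over 18 alternatives its adjusted p ran from 0.0161 to 0.15. The call ended with the Gapdh covariate (0.0693), with scan day as a random block (0.0507), and without G42_Cg array 1 (0.131) or G30_Cg array 1 (0.15). The VIP and CCK list was higher (10 of 12, 10 over the list alone, mean 2.54, adjusted p = 5.12e-23). The parvalbumin list (9 of 12 lower; mean -1.66, adjusted p = 4.75e-15) and all 6 neurofilament genes (mean -2.20, adjusted p = 3.41e-13) were lower, with the same counts over the lists alone. Oxidative phosphorylation genes were lower (37 of 77, 44 over the list alone, mean -0.38, adjusted p = 2.22e-15). The hippocampal pyramidal list was higher through Ccn3 (3.96) and Dkk3 (2.53) (6 of 10 higher, 1 lower, the same over the list alone, adjusted p = 0.000853). The neuropeptide list was higher (7 of 15 higher, 3 lower, the same over the list alone, adjusted p = 0.0124, adjusted p = 0.0646 with an estimated correlation, and 0.833 with the 50th percentile filter). Here 1528 genes were called, 728 higher and 800 lower, 352 of them at least 2-fold.

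Corticothalamic neurons of layer 6 were set against layer 5 neurons of the same cortex to ask how projection type is reflected in expression. Rprm, a regulator of the cell cycle, was higher in CT6_Cg by 4.82 ± 0.19 (SE, n = 3 and 3, 28.2-fold, adjusted p = 2.09e-19), with the adaptor gene Sla (2.78), Trbv1 (2.56), the secreted olfactomedin Olfm3 (2.43) and Tle4, a corepressor of deep-layer neurons (2.26 ± 0.20). C1ql3, a secreted synaptic organizer (-4.83 ± 0.28, 28.4-fold), Lamp5 (-4.5), the calcium channel subunit gene Cacna2d3 (-3.85), Cdh8 (-3.44), the peptide gene Adcyap1 (-3.19), Cck (-2.0 ± 0.15) and Thy1 (-1.43 ± 0.10) were lower. Sst, Pvalb, Gad1, Gad2, Vip and Npy were not called (adjusted p = 0.929, 0.772, 0.724, 0.921, 0.737 and 0.933). The layer 6 list was higher (8 of 11, 8 over the list alone, mean 1.39, adjusted p = 2.22e-15), among them Tbr1 (1.42). The layer 5 list was lower (6 of 14 lower, 2 higher, the same over the list alone, mean -0.55, adjusted p = 0.00845, adjusted p = 0.132 with an estimated correlation, and 0.0765 with scan year as a block), with Parm1 at -3.11 and Nefh at -1.58. Neurofilament genes (4 of 6, 5 over the list alone, mean -0.93, adjusted p = 5.08e-06) and oxidative phosphorylation genes (29 of 77, 44 over the list alone, mean -0.32, adjusted p = 2.22e-15) were lower. The neuropeptide list was lower (4 of 15, 5 over the list alone, adjusted p = 0.0116, adjusted p = 0.0623 with an estimated correlation).

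This comparison called 1169 genes, 557 higher and 612 lower (47.6% higher, and 52.7% with quantile normalization), 184 of them at least 2-fold. With scan year as a block 465 were called (440 shared), with the Gapdh covariate 647 (620 shared), and without YFPH_Cg array 1 or array 2, 722 and 773. The Gapdh log2 3' to 5' signal was 2.86 ± 0.34 (SD) in CT6_Cg and 2.12 ± 0.05 in YFPH_Cg.

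Somatostatin interneurons of the hippocampus were set against those of cingulate cortex to ask how region shapes a subclass. Ramp3, a partner of calcitonin-family receptors, was higher in GIN_Hip by 4.38 ± 0.34 (SE, n = 3 and 3, adjusted p = 1.02e-11), with Ptpre, a receptor tyrosine phosphatase (3.54), the astrocyte enzyme gene Aldoc (3.53), the nociceptin precursor Pnoc (3.35 ± 0.20) and Pvalb (2.47 ± 0.23, adjusted p = 8.76e-10). Bcl11b, a zinc finger transcription factor (-4.06 ± 0.31), Calb2 (-3.38 ± 0.37) and the kinase gene Prkcb were lower. Sst (-0.59 ± 0.36, adjusted p = 0.267), Npy (-0.74 ± 0.35, adjusted p = 0.15) and Gad1 (-0.37 ± 0.33) were not called, nor were Gad2, Vip, Cck and Thy1 (adjusted p = 0.498, 0.909, 0.341 and 0.575). The astrocyte list had 2 of 10 genes higher (2 over the list alone) and a mean level of 9.35 ± 0.16 (SD) in GIN_Hip against 8.88 ± 0.06 in GIN_Cg, and was not called (adjusted p = 0.246). The parvalbumin list was higher (6 of 12; 6 higher and 1 lower over the list alone, mean 0.52, adjusted p = 0.00211). Oxidative phosphorylation genes were higher (35 of 77; 43 higher and 1 lower over the list alone, mean 0.33, adjusted p = 3.39e-12, adjusted p = 0.0553 with an estimated correlation). The neurofilament list was higher (5 of 6, 5 over the list alone, adjusted p = 0.00181, adjusted p = 0.128 with an estimated correlation). In all 1706 genes were called, 913 higher and 793 lower; 1126 without GIN_Hip array 2, 878 with the compared arrays only, and 1035 with the Gapdh covariate (959 shared). The Gapdh log2 3' to 5' signal was 2.43 ± 0.38 (SD) in GIN_Hip and 3.21 ± 0.37 in GIN_Cg.

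Thalamic interneurons of the G42 line were set against the parvalbumin cells of cingulate cortex to ask what region changes in the GABA cells of a line. Of the 4 GABA genes Abat was lower in G42_LGN (-0.45 ± 0.16, adjusted p = 0.0399), while Gad1 (-0.13 ± 0.33), Gad2 (-0.01 ± 0.19) and Slc32a1 (0.21 ± 0.29) were not called. Syt9, a calcium sensor of vesicle fusion, was higher by 5.87 ± 0.31 (SE, n = 3 and 3, 58.6-fold, adjusted p = 9.06e-17), with the complexin gene Cplx3 (5.53), the transcription cofactor gene Lmo1 (4.82 ± 0.21), the protocadherin gene Pcdh20 (4.70) and the growth factor gene Igf1 (4.17). The transcription factor genes Tcf4 (-5.0 ± 0.12, adjusted p = 9.4e-27) and Dlx1 (-4.37 ± 0.24), and Pvalb (-4.12 ± 0.23), Cck (-3.42 ± 0.15) and Npy (-2.77 ± 0.35), were lower. Sst was at -1.11 (adjusted p = 0.0182, from 0.00346 to 0.0877 over 18 alternatives), and this call ended without G42_Cg array 2 (0.0877), G42_Cg array 3 (0.0706) or G42_LGN array 1 (0.0551). Thy1 was at -0.27 ± 0.10 (adjusted p = 0.0484), a call that ended in 11 of 18 alternatives (0.0147 to 0.188), and Vip was not called (0.50 ± 0.21, adjusted p = 0.0831). The parvalbumin list was lower (8 of 12, 9 over the list alone, mean -1.47, adjusted p = 2.2e-10), as were the GABA transcription factors (5 of 9 lower, 1 higher; 6 and 1 over the list alone, mean -1.39, adjusted p = 7.51e-06), the neuropeptides (6 of 15 lower, 1 higher; 6 and 2 over the list alone, mean -0.82, adjusted p = 0.00142) and the somatostatin list (6 of 9 lower, 2 higher, the same over the list alone, adjusted p = 0.00385). Oxidative phosphorylation genes were lower (35 of 77 lower, 4 higher; 36 and 5 over the list alone, mean -0.32, adjusted p = 3.46e-08, adjusted p = 0.141 with an estimated correlation). The list of thalamic and midbrain transcription factors was not called in any comparison (lowest adjusted p = 0.0994). In all 2446 genes were called, 1302 higher and 1144 lower (53.2% higher, and 43.9% with median centring), 481 at least 2-fold, and 1544 with the Gapdh covariate (1490 shared). The Gapdh log2 3' to 5' signal was 2.89 ± 0.12 (SD) in G42_LGN and 1.98 ± 0.20 in G42_Cg.

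G30 interneurons of somatosensory and cingulate cortex differed in few genes when G30_SS was set against G30_Cg to ask about cortical area. The neurofilament genes Nefm (2.34 ± 0.29, SE, n = 3 and 3, adjusted p = 4.42e-06) and Nefl (1.74 ± 0.15, adjusted p = 3.86e-09) were higher in somatosensory cortex, with Nrgn (2.19 ± 0.31) and Itpka (1.73 ± 0.19), genes of excitatory synapses. Nrgn and Itpka were also higher in pyramidal neurons than in interneurons. The mean of the glutamatergic list was 8.95 ± 0.17 (SD) in G30_SS and 8.63 ± 0.06 in G30_Cg. The cause of these differences was not tested. Col19a1, a collagen gene (-0.91 ± 0.20, adjusted p = 0.0463), and Necab2 (-0.52 ± 0.11, adjusted p = 0.04) were lower. Col19a1 ended as a call in 12 of 19 alternatives (adjusted p from 0.000908 to 0.691) and Necab2 in 8 of 20 (0.0167 to 0.554), each among others without G30_Cg array 1 (0.0845 and 0.142), G30_Cg array 2 (0.0929 for both), G30_Cg array 3 (0.344 and 0.188) or G30_SS array 1 (0.398 and 0.259), Col19a1 also without G30_SS array 3 (0.159) and Necab2 without G30_SS array 2 (0.0569). Sst, Pvalb, Gad1, Gad2, Vip, Cck, Npy and Thy1 were not called (lowest adjusted p = 0.884, for Sst). The neurofilament list was higher (2 of 6, 3 over the list alone, mean 0.89, adjusted p = 2.14e-12), as was the glutamatergic list (2 of 12, 3 over the list alone, mean 0.32, adjusted p = 0.000359). The VIP and CCK list was lower although limma called 0 of its 12 genes (4 lower over the list alone, 4 by unadjusted p; mean -0.32, adjusted p = 5.91e-06). The parvalbumin list was higher with 0 of 12 genes called (0 over the list alone, 2 higher by unadjusted p; adjusted p = 0.0116), and not without G30_SS array 2 (adjusted p = 0.075). The layer 5 list was higher (2 of 14; 3 higher and 1 lower over the list alone, adjusted p = 0.00241, adjusted p = 0.0818 with an estimated correlation). In all 17 genes were called, 15 higher and 2 lower (88.2% higher, and 73.9% with quantile normalization), and 10.9% of tested genes had arrays that did not overlap. The count was 33 with scan day as a random block (17 shared) and 10 with it as a fixed block (5 shared), which left Nefm, Nefl, Nrgn and Itpka among the called genes but not Zbtb18, Itgav, Baiap2, Col19a1 or Necab2. With the compared arrays only 1 gene was called, Nefl; without G30_Cg array 1, G30_Cg array 2 or G30_SS array 2 the count was 8, 11 and 34. All called genes kept direction within the shared scan day (2 and 2 arrays), which tests little.

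The same area contrast in layer 5 neurons, YFPH_SS against YFPH_Cg, asked whether pyramidal cells differ by area. Pvalb was higher in somatosensory cortex by 3.18 ± 0.23 (SE, n = 3 and 3, adjusted p = 1.72e-11), with Rcan2, a calcineurin regulator (2.70), Hsd11b1, a glucocorticoid-activating enzyme (2.26), Aldoc (2.03) and Nefh (1.63). Grp, gastrin-releasing peptide (-3.05 ± 0.28), and Nnat, neuronatin (-3.03 ± 0.47), were lower, as were Tubb2b (-2.57) and Cxcl12 (-2.18). Sst, Gad1, Gad2, Vip, Cck, Npy and Thy1 were not called (lowest adjusted p = 0.975, for Cck). The neurofilament list was higher (2 of 6, 5 over the list alone, mean 0.85, adjusted p = 1.54e-09), and so was the parvalbumin list (4 of 12, 4 over the list alone, mean 0.53, adjusted p = 1.44e-05). The hippocampal pyramidal list (2 of 10 lower, 1 higher; 6 and 1 over the list alone, mean -0.55, adjusted p = 4.49e-05), the glutamatergic list (2 of 12, 3 over the list alone, adjusted p = 0.000929) and the neuropeptides (1 of 15, 1 over the list alone, adjusted p = 0.00539) were lower. The astrocyte list was higher through Aldoc and S100b (1.18) (2 of 10 called, 2 over the list alone, mean 0.37, adjusted p = 0.00921, adjusted p = 0.144 with an estimated correlation, 0.0606 without a filter and 0.0513 without YFPH_SS array 2), and its mean level in YFPH_SS, 9.46, was the highest among the sorted groups. In all 147 genes were called, 80 higher and 67 lower (54.4% higher, and 49.3% with median centring), and 12.0% of tested genes had arrays that did not overlap. With scan day as a fixed block the difference rests on 1 array of each group. In that fit Tubb2b stood at -2.496 and Cxcl12 at -1.958, near their values above, and Aldoc (1.178) and Nefh (1.126) were smaller. The count was 52 with the compared arrays only, 93 and 77 without YFPH_Cg array 1 or 2, and 84 and 61 without YFPH_SS array 2 or 3. Within the shared scan day (1 and 1 array) 99.3% of the called genes kept direction, at a median 0.693 of their size, which tests little.

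Hippocampal pyramidal neurons were set against cortical layer 5 cells of the same line to ask how they depart from them. The YFPH_Hip mice were at least 91 days old and the YFPH_Cg mice with a stated age 65 and 80. Dcn, the proteoglycan decorin, was higher in YFPH_Hip than in YFPH_Cg by 5.15 ± 0.36 (SE, n = 3 and 3, 35.6-fold, adjusted p = 1.65e-12), with Calb1 (3.92 ± 0.31), Pcdh20 (3.36) and Nnat (3.21). Lamp5 (-4.15 ± 0.30), the transcription factor gene Mef2c (-3.21 ± 0.18), Ramp3 (-3.04) and Cckbr, a cholecystokinin receptor (-2.38), were lower. Of Sst, Pvalb, Gad1, Gad2, Vip, Cck, Npy and Thy1 none was called (lowest adjusted p = 0.614, for Sst). The hippocampal pyramidal list was higher (6 of 10; 6 higher and 1 lower over the list alone, mean 0.81, adjusted p = 4.13e-05), including Man1a (1.38), Ccn3 (1.30) and Zbtb20 (1.10). Layer 5 genes were lower (5 of 14, 6 over the list alone, mean -0.55, adjusted p = 0.000513). The astrocyte list was lower through Aldoc, S100b, Clu and Glul (4 of 10, 5 over the list alone, mean -0.52, adjusted p = 0.000808, adjusted p = 0.0553 with an estimated correlation). In all 935 genes were called, 415 higher and 520 lower; 566 with the compared arrays only and 582 without YFPH_Cg array 1.

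Amygdala neurons of the YFPH line were compared with the same cortical cells to ask what the amygdala sample adds. The YFPH_Amy mice were at least 91 days old and the YFPH_Cg mice with a stated age 65 and 80. Matn2, a matrix protein gene (3.22 ± 0.28, SE, n = 3 and 3), Prss23 (3.16), Cdkn1c, a cell cycle inhibitor (3.04), and Rprm (2.46) were higher in YFPH_Amy. Ramp3 (-3.27 ± 0.34), Igfbp4, which binds growth factors (-3.11), Cxcl12 (-2.99) and the homeobox gene Meis2 (-2.99 ± 0.26) were lower. Npy was higher (1.15 ± 0.35, adjusted p = 0.0401), a call that ended in 7 of 18 alternatives (4.45e-05 to 0.155). These were scan day as a random block (0.0518), both abnormally amplified arrays left out (0.0502), and YFPH_Cg array 1 (0.129), 2 (0.114) or 3 (0.0683) or YFPH_Amy array 1 (0.155) or 3 (0.131) left out. Sst, Pvalb, Gad1, Gad2, Vip, Cck and Thy1 were not called (lowest adjusted p = 0.491, for Cck). The striatal GABA list was lower (3 of 12, 4 over the list alone, mean -0.43, adjusted p = 0.000942), with Meis2, Foxp1 (-0.71) and Tac1 (-0.57). Genes of layer 5 were lower (4 of 14; 5 lower and 1 higher over the list alone, adjusted p = 0.0025, adjusted p = 0.0827 with an estimated correlation). In all 635 genes were called, 347 higher and 288 lower, 188 of them at least 2-fold.

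GFP neurons of the amygdala in the G30 line had low GABA genes and high glutamatergic genes. The comparison with G30_Cg asked whether region changes the cells marked in this line. Gad1 was lower by -4.03 ± 0.33 (SE, n = 3 and 3, adjusted p = 5.79e-12), Gad2 by -3.61 ± 0.19, Vip by -4.96 ± 0.21, Dlx1 by -4.48 ± 0.24, Npy by -3.30 ± 0.35, Sst by -2.33 ± 0.36 and Cck by -1.29 ± 0.15. Thy1 was higher (0.32 ± 0.10, adjusted p = 0.0197), a call that ended with scan year as a block (0.155), with the Gapdh covariate (0.111), with the compared arrays only (0.0572) and without G30_Cg array 2 (0.197). Pvalb was not called (adjusted p = 0.918). Grp was higher by 5.36 ± 0.28 (41.1-fold, adjusted p = 3.11e-17), with Crym (5.21 ± 0.26), Lypd1, a modulator of acetylcholine receptors (4.96), Rprm (4.67) and Itpka (4.36). All 4 GABA genes were lower, and 11 of 12 glutamatergic genes were higher (12 over the list alone, mean 1.71, adjusted p = 2.14e-12), among them Baiap2 (3.22) and Ptk2b (2.69). The mean of the glutamatergic list was 10.34 ± 0.14 (SD) in G30_Amy, 8.63 ± 0.06 in G30_Cg and 10.52 ± 0.07 in YFPH_Amy. Gad1 varied among the G30_Amy arrays (8.08 ± 1.52), Gad2 little (7.42 ± 0.19). Also lower were the VIP and CCK list (9 of 12, 9 over the list alone, mean -2.16, adjusted p = 2.48e-15), the GABA transcription factors (5 of 9 lower, 1 higher; 6 and 1 over the list alone, mean -0.75, adjusted p = 0.00297), the neuropeptides (6 of 15 lower, 2 higher; 6 and 3 over the list alone, adjusted p = 0.000864, and 0.302 with the 50th percentile filter) and the somatostatin list (5 of 9 lower, 1 higher, the same over the list alone, adjusted p = 0.00414, and 0.112 with every probe set). The parvalbumin list was lower (4 of 12 lower, 1 higher, the same over the list alone, adjusted p = 0.0313, adjusted p = 0.0848 with an estimated correlation), and the neurofilament list was higher (3 of 6, 1 lower, the same over the list alone, adjusted p = 0.0105, adjusted p = 0.223 with an estimated correlation, and 0.124 with every probe set). In all 2332 genes were called, 1297 higher and 1035 lower, and 1169 with scan year as a block (1049 shared). The last scan year held only G30_Amy arrays 2 and 3, so with this block the difference rests on G30_Amy array 1.

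The amygdala neurons of the YFPH and G30 lines were then compared to ask whether both lines mark like cells there. Prss23 (3.73 ± 0.45, SE, n = 3 and 3), Rspo2, a Wnt pathway agonist (3.56 ± 0.28), the calcium-binding S100b (2.56) and Thy1 (1.5 ± 0.10) were higher in YFPH_Amy. Id4 (-2.87 ± 0.27), Gad1 (-2.6 ± 0.33, adjusted p = 4.57e-07) and the cadherin gene Cdh13 (-2.42) were lower, as was Slc32a1 (-1.52 ± 0.29, adjusted p = 0.000317). Gad2 (-0.18 ± 0.19, adjusted p = 0.529) and Abat (0.878) were not called. Cck was higher (0.76 ± 0.15, adjusted p = 0.00032), but not called with scan year as a block (0.297). Sst, Pvalb, Vip and Npy were not called (adjusted p = 0.712, 0.408, 0.545 and 0.18). The layer 5 list (5 of 14; 7 higher and 1 lower over the list alone, mean 0.57, adjusted p = 0.000513) and the neurofilament list (3 of 6, 6 over the list alone, mean 0.83, adjusted p = 1.55e-05) were higher. The hippocampal pyramidal list was higher (4 of 10 higher, 2 lower; 5 and 2 over the list alone, adjusted p = 0.023, adjusted p = 0.0646 with an estimated correlation). In all 1615 genes were called, 856 higher and 759 lower (53.0% higher, and 46.1% with quantile normalization). No scan year held arrays of both groups. With scan year as a block and G30_Amy array 1 alone for that group, Gad1 (-0.68) was not called. The count was 515 with the Gapdh covariate (505 shared), 1024 without the 2 arrays recorded as abnormally amplified (990 shared), 1016 without YFPH_Amy array 2 and 994 without G30_Amy array 3. The Gapdh log2 3' to 5' signal was 2.29 ± 0.27 (SD) in YFPH_Amy and 3.25 ± 0.43 in G30_Amy.

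**Figure D3:**
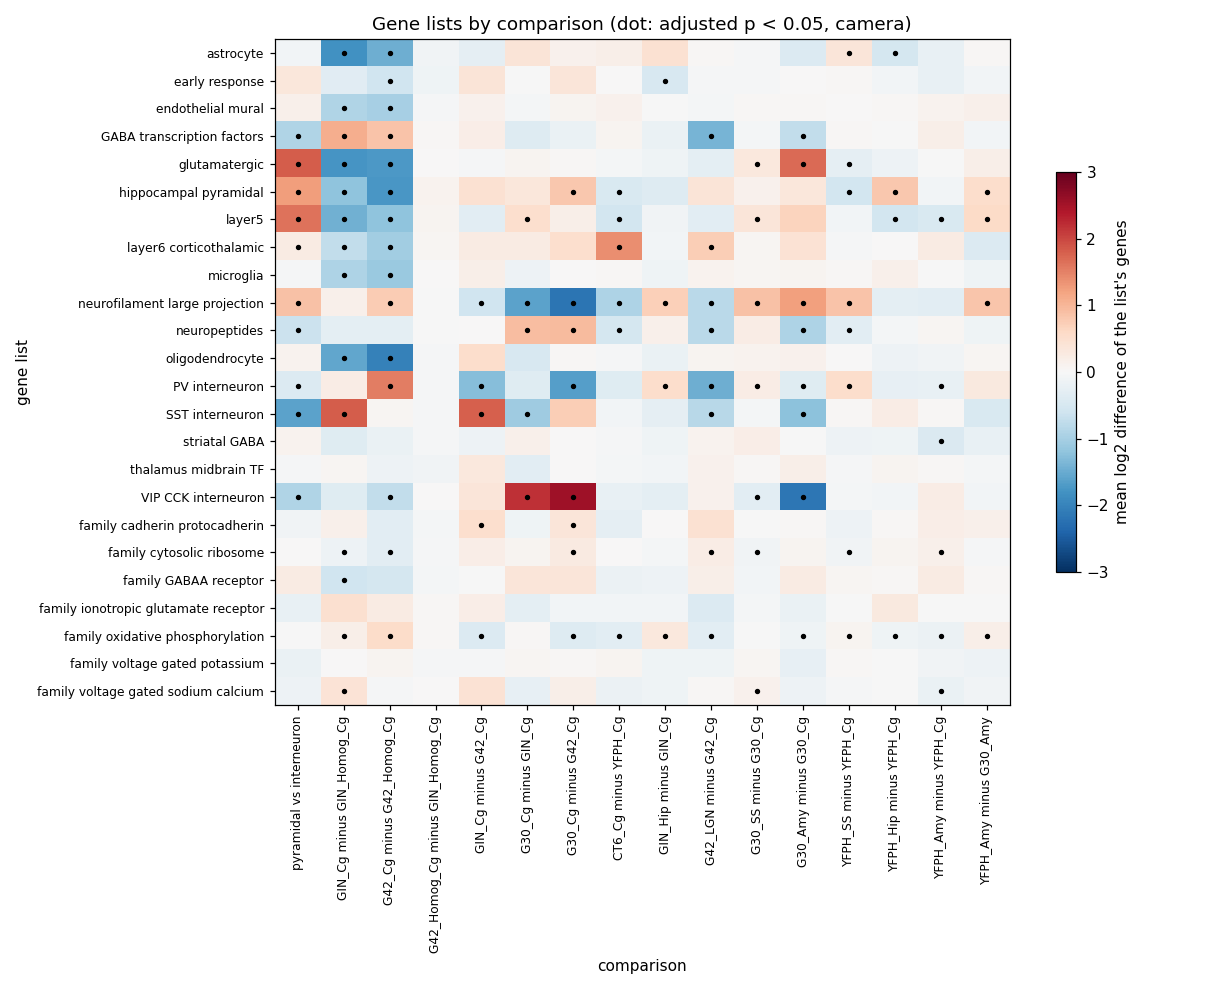
Colour gives the mean log2 difference of each of 24 gene lists (rows) in each of 16 comparisons (columns), and dots mark lists called by camera.

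Whether region acts alike on different lines was asked with interactions, each the region difference of the YFPH line minus that of a GFP line. For hippocampus against cingulate cortex 1946 genes were called, 914 higher and 1032 lower. Ramp3 had an interaction of -7.41 ± 0.48 (SE, n = 3 arrays in each of 4 groups, adjusted p = 1.95e-13), being lower in hippocampus in YFPH (-3.04) and higher in GIN (4.38). Aldoc (-5.23; -1.70 and 3.53) and Igfbp4 (-5.23; -2.28 and 2.96) had the same form, Dcn was at 6.85 ± 0.51, Calb1 at 5.93 ± 0.44 and Pvalb at -2.39 ± 0.33. Sst, Gad1, Gad2, Vip, Cck, Npy and Thy1 had no called interaction (lowest adjusted p = 0.193, for Sst). Across lines 31 genes were higher in hippocampus in both (40.8 by chance) and 40 lower in both (44.4 by chance), among them Eps8 (1.81 and 1.71), chosen after its values were seen, and Pcsk5 (-2.26 and -2.12); 88 and 125 were called in opposite directions (35.4 and 51.1 by chance). With the Gapdh covariate 1229 genes were called for this interaction, 1149 of them shared. The Gapdh log2 3' to 5' signal was higher in hippocampus in YFPH (2.53 against 2.12) and lower in GIN (2.43 against 3.21). The genes called in both lines were not counted again with the covariate.

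For somatosensory against cingulate cortex, YFPH against G30, 43 genes were called for the interaction, 16 higher and 27 lower. Pvalb (2.83 ± 0.33, SE, n = 3 arrays in each of 4 groups, adjusted p = 7.39e-07), Hsd11b1 (2.48) and Rcan2 (2.57) were higher, and Grp (-4.13 ± 0.39), Cxcl12 (-3.22) and Itpka (-2.48) were lower. Sst, Gad1, Gad2, Vip, Cck, Npy and Thy1 were not called (lowest adjusted p = 0.999). Of 147 genes called in the YFPH area contrast and 17 in the G30 one, limma called 0 in the same direction and 2 in opposite directions (0.108 by chance): Itpka (-0.74 in YFPH and 1.73 in G30) and Ltk (-0.60 and 0.74), the last chosen after its values were seen. Without YFPH_SS array 3 the count was 27, and with the compared arrays only 23. For amygdala against cingulate cortex, again YFPH against G30, 1086 genes were called, 536 higher and 550 lower, and 650 with scan year as a block (576 shared), again with G30_Amy array 1 alone for that group. Of the 1086 genes 49.4% were higher, and 50.4% with median centring. The YFPH_Amy mice were older than the YFPH_Cg mice of stated age, so this interaction holds age as well as region. Crym was at -6.34 ± 0.37 (-1.12 in YFPH and 5.21 in G30), Lats2 at 5.73 ± 0.54, Vip at 4.89, Npy at 4.45 ± 0.50, Gad1 at 3.76 ± 0.46, Gad2 at 3.63, Sst at 2.25 ± 0.50 and Cck at 1.52 ± 0.20. Pvalb (adjusted p = 0.95) and Thy1 (0.0876) were not called. In the amygdala 159 genes were higher in both lines (48.4 by chance) and 104 lower in both (32.1 by chance), among them Matn2 (3.22 and 3.28), Grp (1.83 and 5.36) and the glutamate transporter gene Slc17a6 (1.68 and 2.39), the last chosen after its values were seen.

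Of 9295 genes 7422 (79.8%) differed somewhere among the 12 sorted groups in an F test. Type-specific genes, higher in a single sorted group than in each of the other sorted groups, numbered 117. G42_LGN had 34, among them Chrna6, a nicotinic receptor subunit (2.96 above the next group, adjusted p = 8.34e-18), Syt9 (2.51) and Lmo1 (2.30). G42_Cg had 24, among them Cox6a2 (2.44, adjusted p = 3.66e-16) and the tachykinin precursor Tac1 (2.22). CT6_Cg had 15 (Trbv1, 2.50; Tle4, 1.82), GIN_Hip 14 (Id3, an inhibitor of differentiation factors, 2.23), GIN_Cg 13 (Calb2, 1.84; Nppc, a natriuretic peptide, 1.17), G30_Amy 8 (Tshz2, 1.54), YFPH_Hip 6 (Dcn, 3.32), YFPH_SS 2 (Hsd11b1, 1.56; S100b, 0.98) and YFPH_Amy 1 (Cdh9, 0.91). By limma G30_Cg, G30_SS and YFPH_Cg had 0, against 21, 9 and 8 by unadjusted p. Genes shared by close groups cannot count, as Vip in G30_Cg and G30_SS (mean r 0.9708). YFPH_Cg and YFPH_SS are also close (0.9645), so the counts do not rank the types. The total was 63 with the 50th percentile filter. Over the settings GIN_Cg ran from 3 to 21 and YFPH_Hip from 0 to 13.

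**Figure D4:**
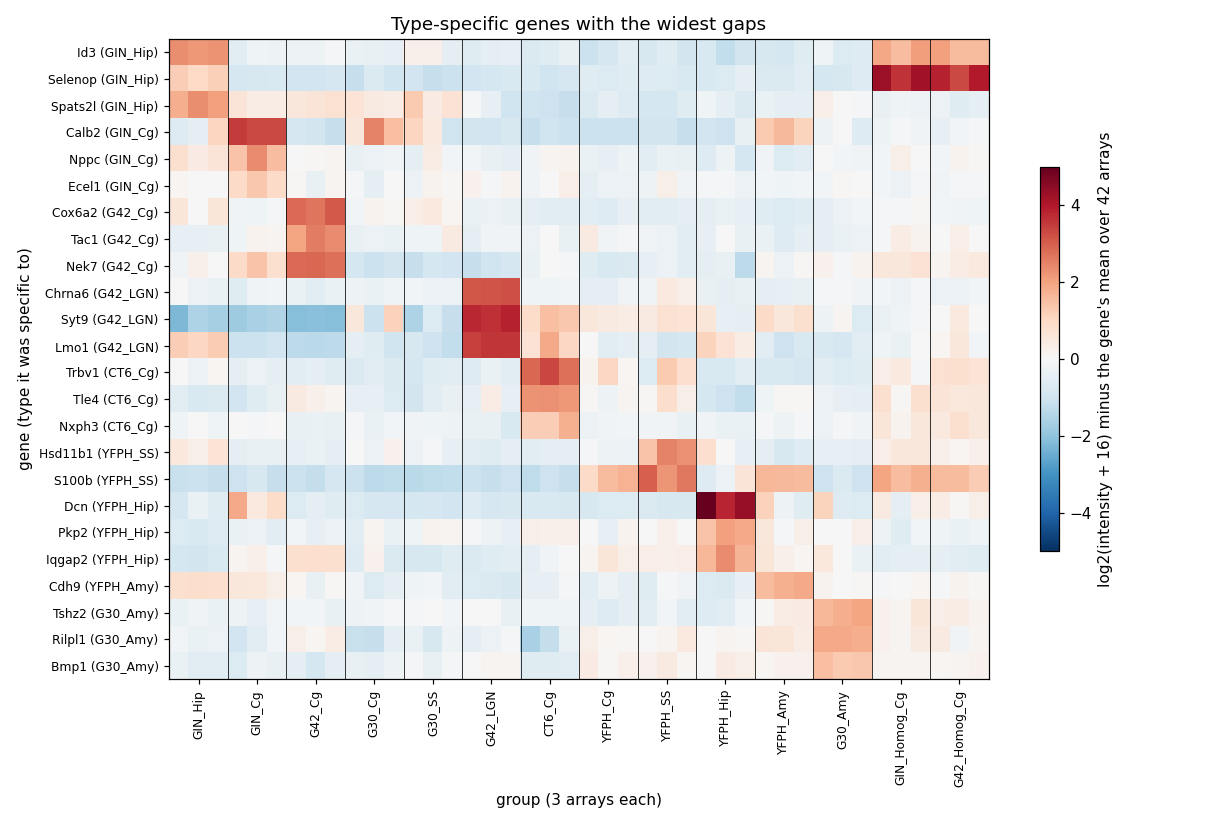
Colour gives log2 (intensity + 16) minus the gene's mean over 42 arrays for 24 type-specific genes (rows) in the 14 groups (columns).

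Oxidative phosphorylation genes were called as a list in 12 comparisons, 4 of them also with an estimated correlation, and ribosomal genes in 7, of which camera called 0 with an estimated correlation. Beyond the comparisons above, oxidative phosphorylation genes were higher in YFPH_Amy than in G30_Amy (18 of 77; 21 higher and 3 lower over the list alone, mean 0.18, adjusted p = 3.85e-05, adjusted p = 0.314 with an estimated correlation). They were lower in YFPH_Amy than in YFPH_Cg (6 of 77, 6 over the list alone, mean -0.17, adjusted p = 5.69e-08, adjusted p = 0.149 with an estimated correlation). In G30_Amy the oxidative phosphorylation list was lower than in G30_Cg (19 of 77 lower and 3 higher, 20 and 3 over the list alone, mean -0.14, adjusted p = 0.00307, adjusted p = 0.492 with an estimated correlation). Ribosomal genes were lower in G42_Cg than in unsorted cells (22 of 45 lower, 2 higher, the same over the list alone, mean -0.32, adjusted p = 0.000143, adjusted p = 0.315 with an estimated correlation). They were higher in G30_Cg than in G42_Cg (7 of 45, 7 over the list alone, mean 0.28, adjusted p = 1.39e-05, adjusted p = 0.245 with an estimated correlation). In G30_SS the ribosomal list was lower than in G30_Cg although limma called 0 of its 45 genes (0 over the list alone, 5 lower by unadjusted p; adjusted p = 4.76e-06, adjusted p = 0.211 with an estimated correlation). Voltage-gated potassium channels (lowest adjusted p = 0.0991) and ionotropic glutamate receptors (lowest adjusted p = 0.236) were not called in any comparison. Of 384 list tests 112 were called, and 67 with an estimated correlation, all of them among the 112. Random regroupings of the arrays gave up to 92. List calls that ended both with an estimated correlation and without a single array are drawn in the heatmap of lists and, apart from astrocyte genes in YFPH_SS, not described here.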

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

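The counts of the 3 interactions were set as values to examine before the data were seen; the split counts were planned too, and all other tests in this part were chosen only after the results were seen. An interaction was marked for a closer look when any gene differed between lines in its region difference: 1946 genes for hippocampus, 43 for somatosensory cortex and 1086 for amygdala. With region labels exchanged within each line, 1 of 100 splits gave as many genes as the 1946 for hippocampus, the real one. The highest other split gave 1004 and kept the regions of the GIN line. For somatosensory cortex 3 of 100 splits gave at least 43. The highest other gave 53 and kept the regions of the YFPH line, and 86 splits that mixed both lines gave at most 4. For amygdala 5 of 100 splits gave at least 1086, the highest being 1401, so chance is not excluded by this count. The 4 others as large all kept the regions of a single line, and 81 splits that mixed both lines gave at most 2 genes. Exchanging labels within a line removes its region difference, so these splits ask whether region matters in either line. They cannot tell whether that difference is unlike between lines, and no verdict on the interactions is drawn from them.

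The unlike region difference in hippocampus was weighed against 4 technical explanations. With the Gapdh 3' to 5' signal as a covariate the count was 1229, so RNA integrity may lie behind part of the genes, but 1149 genes were called with and without it, so it does not account for the whole. Without the abnormally amplified arrays 1917 genes were called, 1725 of them shared, which excludes these arrays as the source. With scan year as a block 2019 genes were called, 1780 of them shared. All YFPH_Hip arrays were of the first scan year and all GIN arrays of the second. The 2 years were linked only within YFPH_Cg and YFPH_SS, through YFPH_Cg array 3 and YFPH_SS array 2, so scan year stays open. The YFPH_Hip mice were at least 91 days old and those of YFPH_Cg with a stated age 65 and 80, and this difference in age was not tested and stays open, as it does for YFPH_Amy, whose mice were also at least 91 days old, and for the amygdala interaction. That region acts differently on pyramidal cells and somatostatin interneurons remains a hypothesis.

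The low GABA genes and high glutamatergic genes of G30_Amy were weighed against mixing and scan year. If excitatory neurons had been mixed into sorted interneurons, GABA genes would keep part of their intensity; over 6 GABA genes the median kept was 8.69% in the highest of the 3 arrays (0.872% and 1.3% in the others). The bounds of this test were set after its value was seen. A sort made up mostly of wrongly picked excitatory neurons would keep as little. Gad1 kept 0.86%, 12.9% and 7.99% in the 3 arrays and Slc32a1 0.883%, 13.7% and 7.46%, so mixing stays open. With scan year as a block the glutamatergic list was still higher by 1.853, but the last scan year held only G30_Amy arrays 2 and 3, so this value rests on G30_Amy array 1 and scan year stays open too. Whether the GFP cells of the amygdala are excitatory in this line was not settled by these tests.

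The difference between pyramidal neurons and interneurons was weighed against scan year and cells of other types. On arrays of the second scan year alone 2136 genes were called, which excludes scan year as the source of the whole pattern. The pyramidal arrays of that year were of CT6_Cg, YFPH_Cg and YFPH_SS, not of YFPH_Hip. Of the genes called over all arrays 94.1% had the same direction there, and 100% of the 315 that differed at least 2-fold. These genes were chosen in part from the same arrays, so those shares test little. On the scan days with 1 array of each class the share was 80.4% and 74.5%. Scan year stays open for part of the genes. Of the 4 lists of glial and vessel cells 0 were called by camera, so cells of these types in the pyramidal sorts are unlikely to explain it.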

How the results depend on the processing

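Chosen only after the results were seen were scan year, the Gapdh covariate, the second scan year alone and list shifts by scan day. So was leaving out the abnormally amplified arrays or YFPH_Cg array 3. The others were planned. Over all settings other than leaving out single arrays in turn, 232 counts moved by at most 1.5 times and 39 by more, and of the type-specific counts of single types 95 and 37. Of named-gene values 3940 kept their state (called or not) and 66 lost a call, and of list values 1234 kept it, 87 lost a call (45 with the estimated correlation) and 1 turned. The list that turned was neuropeptides in G30_Cg minus GIN_Cg, at -0.027 with the 50th percentile filter (adjusted p = 0.755). No called list turned with quantile normalization or median centring. Every probe set, which tests more features by construction, gave 7139 for the class contrast, 4283 for GIN_Cg and 4732 for G42_Cg against unsorted cells, 4 for the unsorted pair, 4301 for GIN_Cg against G42_Cg, 3674 for G30_Cg against GIN_Cg, 1758 for CT6_Cg against YFPH_Cg, 3597 for G30_Amy against G30_Cg, 2594 for YFPH_Amy against G30_Amy, 2928 and 65 for the interactions of hippocampus and somatosensory cortex, 11976 in the F test and a similarity difference of 0.07519. That difference was 0.04699 without a filter and 0.1243 with the 50th percentile filter. Scan year as a block gave 1926 for the class contrast, 465 for CT6_Cg against YFPH_Cg, 1169 for G30_Amy against G30_Cg, 144 for YFPH_Amy against G30_Amy, 650 for the amygdala interaction and 64 type-specific genes; with that block G30_Amy is estimated from its array 1 alone. The Gapdh covariate gave 1773 for GIN_Cg against unsorted cells, 1328 for GIN_Cg against G42_Cg, 647 for CT6_Cg against YFPH_Cg, 1035 for GIN_Hip against GIN_Cg, 1544 for G42_LGN against G42_Cg, 515 for YFPH_Amy against G30_Amy and 1229 for the hippocampus interaction. Scan day gave 33 as a random and 10 as a fixed block for G30_SS against G30_Cg. YFPH_SS against YFPH_Cg also moved with the fixed block, on 1 array of each group. The compared arrays only gave 0 by limma for the unsorted pair, 878 for GIN_Hip against GIN_Cg, 1 for G30_SS against G30_Cg, 52 for YFPH_SS and 566 for YFPH_Hip against YFPH_Cg, and 23 for the somatosensory interaction. The class contrast had 584 genes with each cell type as 1 replicate and 2136 in the second scan year. The estimated correlation left 67 list calls, and without the abnormally amplified arrays YFPH_Amy against G30_Amy had 1024 genes. The cause of these moves was not tested. With a single array left out, 249 counts moved by at most 1.5 times and 21 by more, and of the type-specific counts of single types 409 and 23. Over the other settings the count per type ran from 5 to 20 in GIN_Hip, 3 to 21 in GIN_Cg, 13 to 33 in G42_Cg, 0 to 2 in G30_Cg, 19 to 51 in G42_LGN, 7 to 23 in CT6_Cg, 0 to 1 in YFPH_Cg, 1 to 4 in YFPH_SS, 0 to 13 in YFPH_Hip, 0 to 4 in YFPH_Amy and 2 to 13 in G30_Amy, and by limma it stayed at 0 in G30_SS. With a single array left out it ran from 9 to 15, 6 to 19, 16 to 25, 0 to 2, 24 to 36, 13 to 17, 0 to 2, 1 to 4, 3 to 8, 1 to 3 and 5 to 10 in the same order. From lowest to highest, the counts were 7205 to 7589 in the F test, 102 to 122 type-specific genes, 107 to 114 lists, 4282 to 4712 for the class contrast, 2164 to 2475 and 2552 to 2687 for GIN_Cg and G42_Cg against unsorted cells, 0 to 2 for the unsorted pair, 2068 to 2643 for GIN_Cg against G42_Cg, 1504 to 2324 for G30_Cg against GIN_Cg, 1104 to 1447 for G30_Cg against G42_Cg and 722 to 1289 for CT6_Cg against YFPH_Cg. For regions they were 1126 to 2017 for GIN_Hip, 1891 to 2143 for G42_LGN, 8 to 34 for G30_SS, 1720 to 2376 for G30_Amy, 61 to 213 for YFPH_SS, 582 to 922 for YFPH_Hip and 439 to 533 for YFPH_Amy, each against its cingulate group, 994 to 1472 for YFPH_Amy against G30_Amy, and 1495 to 1997, 27 to 63 and 860 to 1157 for the interactions of hippocampus, somatosensory cortex and amygdala.

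With the replicate number as a block, which tests pairing by that number only, the counts were 4576 for the class contrast, 2730 and 3004 for GIN_Cg and G42_Cg against unsorted cells, 1 for the unsorted pair, 2727, 2309 and 1534 for GIN_Cg against G42_Cg and G30_Cg against each, 1173 for CT6_Cg against YFPH_Cg, 1696 for GIN_Hip, 2453 for G42_LGN, 15 for G30_SS, 2341 for G30_Amy, 151 for YFPH_SS, 967 for YFPH_Hip and 649 for YFPH_Amy against their cingulate groups, 1602 for YFPH_Amy against G30_Amy, 1945, 44 and 1096 for the interactions, 7377 in the F test, 114 type-specific genes and 113 lists. Of the named genes, Itgav and Col19a1 in G30_SS against G30_Cg were not called with this block, and no other call of a named gene changed. Outside the unsorted pair the numbers are not shown to pair the arrays. Some arrays of the same age and scan day carried different numbers, such as YFPH_Hip array 1 and YFPH_Amy array 2. The block does not test a pairing of that kind.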

Other observations

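All tests named in this part beyond the planned splits were chosen only after the results were seen. Gene by gene, region differences ran against each other between lines in hippocampus (r = -0.181 over all genes) and with each other in somatosensory cortex (0.197) and amygdala (0.229), from groups that share no array. The Gapdh log2 3' to 5' signal also ran in opposite directions in the hippocampus lines. The correlation was not repeated with the Gapdh covariate. Sorted cells of both GFP lines departed from their unsorted cells alike: 656 genes were higher in both (222 by chance) and 820 lower in both (220 by chance), with r = 0.644. Among the G30_Amy arrays Gad1, Slc32a1 and Npy varied widely while Gad2 was low on each. Id3 and Selenop, specific to GIN_Hip among the sorted groups (log2 10.26 and 9.23), were also high in the unsorted cells of both the GIN line (9.87 and 12.12, n = 3) and the G42 line (9.74 and 11.79, n = 3).

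Arrays of different regions from mice of the same age, hybridized on the same scan day, deviated from their group means together, with r = 0.068 and 0.156 in G30 cortex, 0.293 in YFPH cortex, and 0.366, 0.289 and 0.251 between YFPH_Hip and YFPH_Amy. The cause was not tested.

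In each pair of groups other than the unsorted cells, 1 of the 10 splits of 6 arrays gave as many genes, the real one, and 10 splits are too few to give a share under 0.05. The real value and the highest other split were 2731 and 0 for GIN_Cg against its unsorted cells, 3010 and 2 for G42_Cg against its own, 2735 and 10 for GIN_Cg against G42_Cg, 2296 and 8 for G30_Cg against GIN_Cg, 1528 and 0 for G30_Cg against G42_Cg, and 1169 and 1 for CT6_Cg against YFPH_Cg. They were 1706 and 245 for GIN_Hip against GIN_Cg, 2446 and 4 for G42_LGN against G42_Cg, 17 and 5 for G30_SS against G30_Cg, 2332 and 1 for G30_Amy against G30_Cg, and 147 and 6 for YFPH_SS against YFPH_Cg. They were 935 and 2 for YFPH_Hip, 635 and 1 for YFPH_Amy, each against YFPH_Cg, and 1615 and 8 for YFPH_Amy against G30_Amy. The unsorted groups gave 1 gene, as many or more in 4 of 10 splits and 5 in the highest; 4 of the splits part all 3 pairs of arrays with the same number, and those other than the real one gave 0 genes by limma.

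For the class contrast 100 of the 210 possible sets of 4 of the 10 types were counted, and 1 of 100, the real one, reached 4562 genes. The highest other set, GIN_Cg, G30_Cg, G30_SS and G42_LGN, with 0 pyramidal types, gave 4432. Each set parts distinct cell types, so this rank cannot exclude chance. Regrouped arrays gave at most 375 genes against 7422 in the F test (1 of 100), 8 against 117 type-specific genes (1 of 100), and 92 list calls against 112 (1 of 100). Chance is excluded for the F test count, the type-specific count and the total of list calls. Regroupings came near the total of list calls, so that total does not put any single list call beyond chance.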
